A study of Homo sapiens with 2 samples.

How the data were processed

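RNA was measured by RNA-seq in 2 libraries of HES2, an established human embryonic stem cell line, grown with Activin A and basic FGF. One library came from cells given a scrambled control sequence and the other from cells given a short hairpin against MTA2 (shMTA2). The libraries were made from 1 µg of total RNA each, per the labels' protocols. The aligner Bowtie 0.12.2 and the genome build hg19 were named, per the submitters' processing notes, and the step at which each was used is not given in the sources used here. The read counter, the gene annotation, the scaling between the libraries, the strandedness and the statistical test are not given in the sources used here.

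The data analysed were 1 table that the authors deposited, with 236 genes in rows. Its 2 columns of expression values hold log2 values, per the file headers and the values themselves. When 2 is raised to each of these deposited log2 values the result is a whole number, within 1e-06, in every row of both columns. The underlying numbers may therefore be read counts, counts with a constant added, or scaled counts rounded to whole numbers, and the table does not say which. They were treated as normalized values of unknown depth, and no counting interval or detection limit was computed. The authors' deposited log2 fold change equals the shMTA2 value minus the scramble value in every row. The authors' deposited p-values lie between 0.0346 and 0.0498, and their deposited FDR is 0.922 in every row, so every listed gene has an unadjusted p below 0.05. Genes outside these rows were not analysed here. A further 2 columns of values, with headers that name no sample, were not used.

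For each gene the difference was taken as the log2 value in shMTA2 minus that in scramble, with nothing added before the logarithm. A constant of 1 had been planned for values without counts and was left out after the values were seen, because they were deposited on the log2 scale and none was below 15. Differences with the constant of 1 are among the alternatives. There was 1 library per group. The differences therefore have no replicate check, no p-value was computed, and every statement describes these 2 libraries. The authors' p-values compare the same 2 libraries, not the conditions. A gene was counted as higher or lower when it differed at least 2-fold and had a value of at least 1 in at least 1 library. The rule had been fixed with a counting interval for use on read counts, and with no interval for data without counts, which is the form used.

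The genes to be named were fixed before the data were examined. They were MTA2 and the other subunits of its complex, the 12 genes with the largest and the 12 with the smallest log2 difference among those with a value of at least 5 in at least 1 library, up to 4 genes from each of 37 gene lists, and 18 symbols of marker and reference genes. The 37 lists held 697 symbols for pluripotency, germ layers and other lineages, signalling pathways, cell cycle, stress, metabolism and chromatin complexes. Genes named outside this rule are said to have been chosen after their values were seen. The percentile of each list among random lists matched on expression had been planned with 10000 draws and was not computed, since the rows hold only genes selected for a large difference.

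Ensembl identifiers were looked up in GENCODE release 29, an annotation of GRCh38, for gene type, chromosome and overlapping genes. Of the 236 identifiers, 234 matched, and 229 symbols were the same. Because the submitters' notes name hg19, no coordinates are printed. Cellular component and pathway annotations were taken from the authors' deposited table. The relation between size of difference and level was described with Spearman's rho across genes and a polynomial curve of degree 4 of log2 absolute difference on the mean log2 level. An offset was taken as the constant for which higher and lower genes shared 1 curve, with its SD over 200 resamplings of the genes. The offset fit was tested on simulated tables of 236 genes, where true offsets of -0.3, 0 and 0.3 gave mean estimates of -0.302, -0.0022 and 0.3013. The simulations selected no rows by the size of the difference. They therefore do not show that the fit recovers an offset between the libraries from selected rows. Directions were shuffled across genes 10000 times, freely and within 4 strata of level. Alternatives were constants of 0.1, 1 and 5 added before the logarithm, other limits on low values, fold limits of 1.5 and 4, centring on the median gene, and a shift of the scaling by 0.5 log2. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.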

Results

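The comparison asked which genes differ in expression between HES2 human embryonic stem cells given a hairpin against MTA2 and control cells. MTA2 is a subunit of the nucleosome remodelling and deacetylase (NuRD) complex, a chromatin complex that joins histone deacetylases to a nucleosome remodeller. There were 2 libraries, 1 from cells given a scrambled control and 1 from cells given the hairpin (shMTA2), with no replicates. The table covers 236 genes, whose values ranged from 16 to 30989 in scramble and from 15 to 63901 in shMTA2. These values are whole numbers that the authors deposited as log2. The depth of the libraries is unknown, and differences are shMTA2 minus scramble on the log2 scale.

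MTA2 had no row in the table, so the level of the targeted gene, which would check the labels, was not analysed here. Among genes higher in shMTA2 were CDKN2B, which encodes the CDK4/6 inhibitor p15INK4B (8.62-fold), SOX10, a transcription factor of the neural crest (11.3-fold), and the BMP ligand BMP7 (3.18-fold) with the BMP-induced inhibitor ID2 (4.93-fold). CDKN2B (37) and SOX10 had low values in scramble, and ETS1 of the same neural crest list was 2.96-fold lower. Only 2 of the 18 symbols in the BMP signalling list had a row. Among genes lower in shMTA2 were the thyroid hormone receptor THRB (10.8-fold), the neurotrophin receptor NTRK3 (8.72-fold), the class IIa histone deacetylase HDAC9 (6.64-fold) and asparagine synthetase, ASNS (2.54-fold).

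Of the 236 genes, 128 were higher and 108 were lower in shMTA2. The higher genes differed by 2.1-fold to 17.1-fold, with a median log2 difference of 2.25. The lower genes differed by 2.37-fold to 19.5-fold, with a median of -1.85. By annotation 212 were protein-coding genes, 113 of them higher and 99 lower. There were 17 non-coding RNA genes, 10 higher and 7 lower, and 5 pseudogenes. In the authors' deposited table no gene passed an FDR of 0.05, since the FDR was 0.922 throughout, and all 236 had an unadjusted p below 0.05. Centring on the median listed gene, whose difference was 1.48, left 52 higher and 108 lower genes and gave 10 of the higher genes a negative difference. That outcome is fixed by the makeup of the table, which holds no difference between -1.24 and 1.07, so the centred values given below do not measure an error of the scaling. Subtracting a positive median lowers every difference, which by itself does not show the higher genes to be less stable than the lower ones. The size of the differences followed the level of the gene, with a Spearman's rho of -0.99 between the mean log2 level and the absolute log2 difference. The authors' deposited p-values for these rows all lay between 0.0346 and 0.0498. Rows confined to so narrow a range could give such a rho through their selection alone, so it does not describe expressed genes in general. This rho is across genes, which are not independent replicates. Direction also varied with level. Below a mean log2 level of 7, 27 genes were higher and 3 lower, and at 12 or above 8 were higher and 17 lower. The 12 genes with the largest difference had values of 16 to 39 in scramble, and the 12 with the most negative difference had 15 to 81 in shMTA2.

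**Figure D1:**
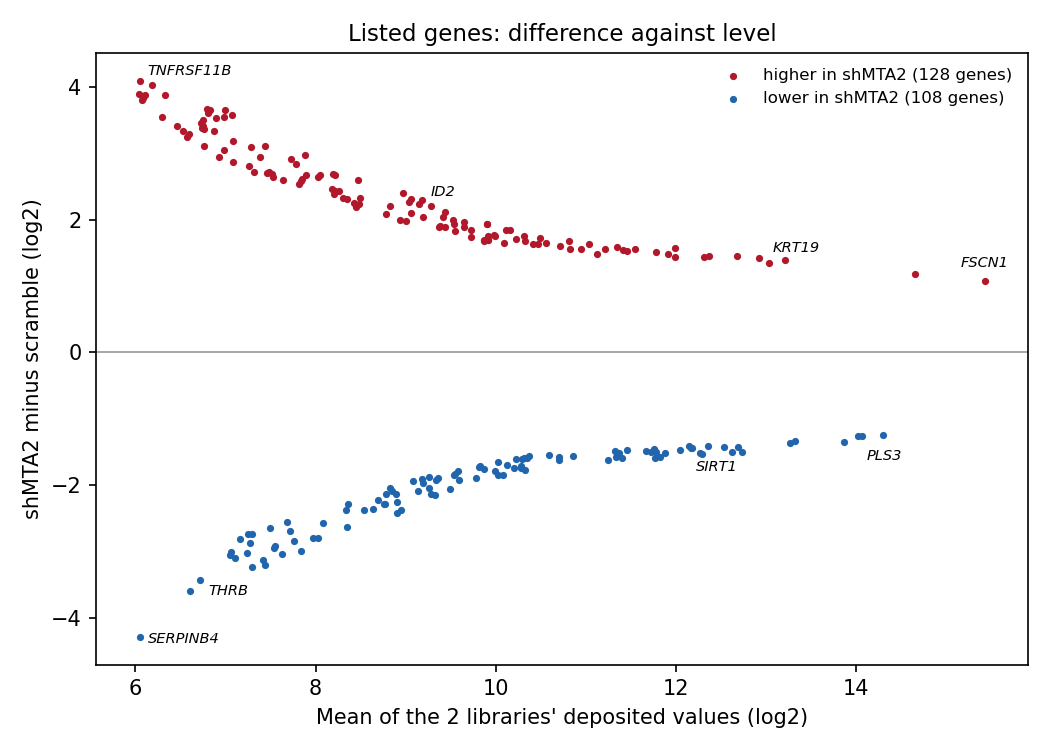
Difference between the libraries (shMTA2 minus scramble, log2) against the mean of the 2 deposited log2 values, with 1 point per gene, red for the 128 higher and blue for the 108 lower genes. The points form 2 narrow bands that approach 0 as the level rises, from 4.09 and -4.29 at the low end to 1.07 (FSCN1) and -1.24 (PLS3) at the high end, and these 2 actin-bundling genes and SIRT1 were chosen for labels after their values were seen.

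Among the 12 genes with the largest difference, 9 were protein-coding. TNFRSF11B, which encodes osteoprotegerin, a secreted decoy receptor for RANKL, went from 16 in scramble to 273 in shMTA2, a 17.1-fold difference. CHL1, a neural cell adhesion molecule of the L1 family, went from 17 to 253, and NTNG2, a netrin-G adhesion protein, from 36 to 453. CNGA4, a subunit of cyclic nucleotide-gated channels, had 18 and 257, and CFAP77, a protein of cilia and flagella, had 31 and 395. ERVW-1, which encodes the fusogenic placental envelope protein syncytin-1, was 14.7-fold higher, and RGPD3 was 16.3-fold higher. Both belong to families with similar copies, so their values are uncertain where reads could be shared. The readthrough gene STX16-NPEPL1 and AC004922.1 were 11.9-fold and 12.6-fold higher, and each overlaps other genes on its own strand. The remaining 3 were the non-coding RNA genes AP001065.2 (14.8-fold) and AC084816.1 (12.2-fold) and the pseudogene AL356052.1 (14-fold).

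Among the 12 genes with the most negative difference, 10 were protein-coding. SERPINB4, a serine protease inhibitor of squamous epithelia with the near-identical copy SERPINB3, went from 293 in scramble to 15 in shMTA2, 19.5-fold lower. THRB went from 346 to 32, and HES3, a basic helix-loop-helix repressor, from 483 to 51. DEPTOR, an inhibitor of the kinase mTOR, was 9.23-fold lower, and NTRK3 was 8.72-fold lower. KLHL26, ILDR2 and MGAT4C were 8.6-fold, 8.26-fold and 8.13-fold lower. AL049844.1 (12.1-fold) overlaps LTV1 and PHACTR2 on the same strand, and BX088645.1 was 8.35-fold lower. The non-coding RNAs were LINC00599 (7.99-fold), which overlaps the microRNA gene MIR124-1, and AC048344.4 (8.02-fold), which overlaps BICD1.

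Of the 697 symbols in the 37 lists, 15 had a row, 8 higher and 7 lower. In the BMP signalling list both genes with a row were higher. ID2 went from 262 to 1291 (4.93-fold), and BMP7 went from 1008 to 3210 (3.18-fold). Centred on the median listed gene, both were under 2-fold, with log2 differences of 0.82 (ID2) and 0.19 (BMP7). In the list for ATF4 and the unfolded protein response both were lower. SLC7A11, a subunit of the cystine/glutamate antiporter, went from 8470 to 2940 (2.88-fold), and ASNS from 16281 to 6421 (2.54-fold). The other members of these lists, 16 in each, had no row.

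In 3 further lists the 2 genes with a row differed in opposite directions. Among neural crest genes SOX10 went from 32 to 361 (11.3-fold higher), and ETS1 was 2.96-fold lower. Among epithelial genes the keratin KRT19 went from 5220 to 13325 (2.55-fold higher), and the tight junction protein TJP3 was 3.46-fold lower. The log2 difference of KRT19 was 1.35, and -0.13 when centred on the median listed gene. Among matrix and integrin genes the integrin subunit ITGAV was 3.02-fold higher (a log2 difference of 0.11 when centred) and ITGA6 was 3.07-fold lower. SOX10 overlaps POLR2F on the opposite strand. The strand of the reads is not given in the sources used here, so the values of the 26 of 38 named genes that overlap another gene are uncertain.

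A further 5 lists had 1 gene with a row. CDKN2B, which overlaps the antisense gene CDKN2B-AS1, went from 37 to 319 (8.62-fold higher). KIT, the stem cell factor receptor in the definitive endoderm list, went from 775 to 2415 (3.12-fold higher), with a log2 difference of 0.16 when centred. ERVW-1, given above, was the only member of the trophoblast and amnion list with a row. HDAC9 went from 392 to 59 (6.64-fold lower). PTPRZ1, a receptor phosphatase in the primed pluripotency list, went from 7365 to 2763 (2.67-fold lower).

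**Figure D2:**
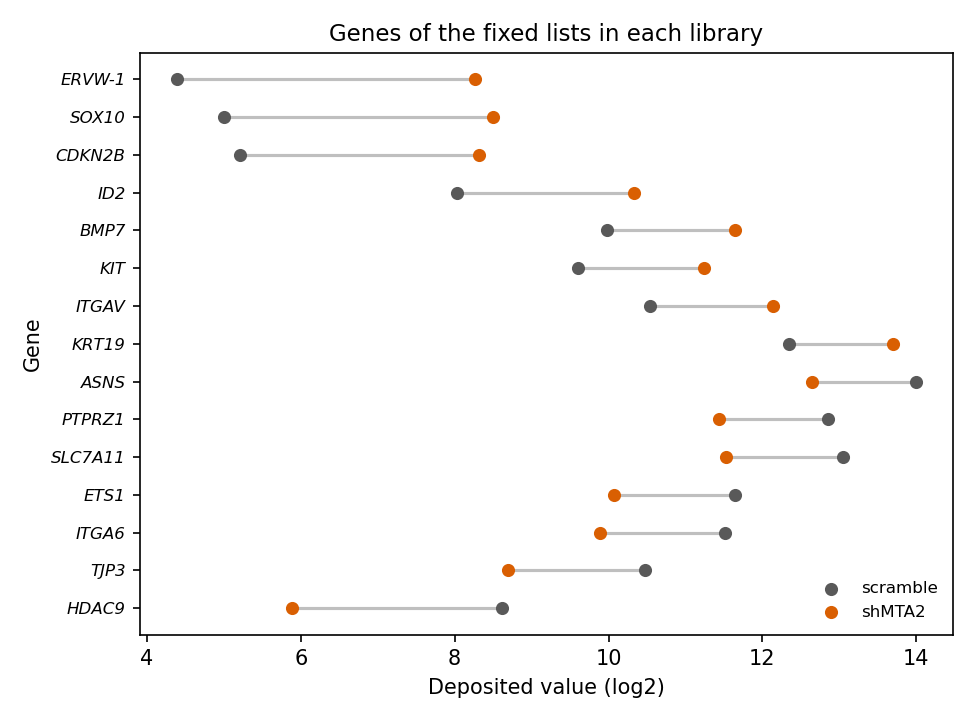
Deposited log2 values of the 15 genes from the fixed lists in the scramble (grey) and shMTA2 (orange) libraries, 1 point per library, joined by a line per gene and ordered by difference. The 8 genes from ERVW-1 to KRT19 are higher in shMTA2 on the deposited scaling and the 7 from ASNS to HDAC9 are lower. When centred on the median listed gene, ID2, BMP7, KIT and ITGAV are under 2-fold and KRT19 is negative, a shift fixed by the makeup of the table.

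The pluripotency factors POU5F1, NANOG and SOX2 had no row. The same was true of TBXT, EOMES, MIXL1, SOX17, GATA4, GATA6, PAX6, CDX2, GATA3, CDKN1A, CDH1, CDH2, ACTB and GAPDH, and of all 15 NuRD symbols, among them MTA1, MTA3, CHD4, HDAC1, HDAC2, MBD3 and RBBP4. No gene of the other 27 lists had a row. These were the lists for the NuRD complex, pluripotency, the naive state, primitive streak and mesendoderm, mesoderm, neuroectoderm, Activin/Nodal, FGF/MAPK, WNT and Notch signalling, mesenchymal genes, fibroblasts or feeder cells, p53 targets, G1/S and G2/M phases, interferon response, heat shock, glycolysis and hypoxia, cholesterol synthesis, oxidative phosphorylation, the cytoplasmic ribosome, Polycomb, histone genes, HOX genes, germ line, immediate early genes and reference genes. The absence of a row gives no value for these genes, the markers of fibroblasts or feeder cells (the other cell type such a culture could hold) included. Related genes outside the fixed lists did have rows, so a list without a row does not mean that its process has none. The examples here are not a full count and were chosen after their values were seen. RBPJ of the Notch pathway was 2.84-fold lower, the Polycomb group gene PHC3 5.39-fold lower and the fibroblast growth factor FGF16 6.25-fold lower. The WNT pathway regulator APC was 6.25-fold higher and the histone variant gene H2AFY 2.68-fold higher (negative when centred).

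In the pathway annotation of the authors' deposited table, 82 genes were assigned to at least 1 KEGG pathway. The pathways named here were chosen after the values were seen. Focal adhesion held 5 listed genes, 4 of them higher, against 128 of all 236 listed genes. The like comparison would be with the 82 assigned genes, whose share of higher genes was not computed. ECM-receptor interaction held 4, with 3 higher. These 4 (COL2A1, COL9A2, ITGA6 and ITGAV) are all among the focal adhesion genes, so these pathways are not separate sets. Thyroid hormone signalling held 5, of which 4 were lower, and cAMP signalling held 7, with 4 higher and 3 lower. No enrichment was tested, because the genes from which the rows were selected are not part of the table used here.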

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

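The shift of the scaling, the constant of 5 and the use of no constant for the reported differences were chosen after the data were seen. The counts of 128 higher and 108 lower genes were the same with constants of 0.1, 1 or 5 added before the logarithm. This says little about stability, since genes nearest the 2-fold limit had high values, such as FSCN1 (30472 in scramble), which such constants barely move. No limit on low values, a minimum of 5, the authors' log2 ratio and a fold limit of 1.5 could not alter the counts. The lowest value was 15, the smallest fold 2.1 and the authors' ratio equal to the difference, so these say nothing about stability. A fold limit of 4 left 74 higher and 45 lower genes. Centring on the median listed gene, a shift by 1.48 log2, left 52 higher genes and 108 lower ones, which the makeup of the table fixes: it holds only selected genes, none between -1.24 and 1.07, and its median is not that of all expressed genes. That centring turned the median of the neural crest list from 0.97 to -0.51 and KRT19 from 1.35 to -0.13. It left 5 of the named higher genes (ID2, BMP7, KIT, ITGAV and KRT19) under 2-fold. It moved the medians of the BMP signalling list from 1.99 to 0.51, of the ATF4 list from -1.43 to -2.91, of the epithelial list from -0.22 to -1.7, and of the matrix and integrin list from -0.01 to -1.49. A scaling shifted by 0.5 log2 towards scramble left 117 higher genes, and one towards shMTA2 left 88 lower genes. A constant of 5 moved 24 of the 38 named genes by over 0.1 log2, by up to 0.39 in any gene, and a constant of 1 by up to 0.09. The count of genes in the authors' deposited table at an FDR of 0.001 was 0, as at 0.05, because the FDR is 0.922 throughout. TMM and size-factor scaling, library totals, counting intervals and random-list percentiles were not run, since these need read counts or genes outside the selection. No paired analysis was possible because there was 1 library per group. Depth is unknown, so which of the low values could come from counting error alone cannot be said.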

Other observations

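The tests in this part were all chosen after the results were seen, as were the genes named here outside the fixed rule. The latter include chromatin and transcription regulators of both directions, for which no list was tested as a group. MIER1, a scaffold that binds the deacetylases HDAC1 and HDAC2, went from 1257 in scramble to 332 in shMTA2 (3.79-fold lower), and the deacetylase SIRT1 from 7628 to 2804 (2.72-fold). PHC3, a Polycomb group protein, was 5.39-fold lower, the corepressor BCOR and the acetyl-lysine reader CECR2 were each 2.82-fold lower, and RBPJ, the DNA-binding partner of Notch, was 2.84-fold lower. In the other direction, ZFPM1, a GATA cofactor known to recruit NuRD, went from 163 to 743 (4.56-fold), and the lysine methyltransferase SETD7 was 3.3-fold higher; both were under 2-fold when centred on the median listed gene, a shift fixed by the makeup of the table. Of the 9 genes annotated as mitochondrial part, 8 were lower, and of the 16 annotated as mitochondrion 10 were lower. For mitochondrial part, 96 of 10000 free shuffles of the directions were as skewed towards lower. Within strata of level 285 shuffles were, for 1 term picked from 78. The lower genes of the mitochondrial part included GLDC of the glycine cleavage system (2.85-fold), the transaminase GPT2 (3-fold) and proline dehydrogenase, PRODH (2.79-fold).

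Genes annotated to the extracellular region leaned higher, with 35 of 51 higher, and nucleoplasm genes leaned lower, with 22 of 34 lower, against 105 of 196 annotated genes higher. The higher extracellular genes included the collagens COL2A1 (3.8-fold) and COL9A2 (3.38-fold), both under 2-fold when centred. Both terms were picked from 78 for their skew. Chance over many terms stays open. In 1813 of 10000 free shuffles of the directions the most one-sided term was as one-sided as the observed one. One-sidedness was measured here by a 2-sided hypergeometric score, which depends on the number of genes in a term as well as on the share. By that score the observed term was membrane part, with 50 of 76 genes higher. Smaller terms had larger shares, such as mitochondrial part with 8 of 9 lower. The count of shuffles with a term as one-sided was 2542 of 10000 when directions were shuffled within strata of level. It cannot decide on the level of the genes, because free shuffles already gave terms as one-sided that often. Counts for single terms took only skews in the observed direction. The counts of 1813 and 2542 took either direction, so the 2 kinds are not alike. For the extracellular region 87 free shuffles and 45 within strata were as skewed, and for the nucleoplasm 148 and 197. Strata of level therefore did not remove these skews. For membrane part the counts were 49 and 228, a weaker skew within strata. None of these counts excludes chance for terms chosen in this way. These shuffles treat genes as exchangeable, which they are not, and describe only these 2 libraries. Loss of MTA2 could also underlie the pattern, as could any other difference between 2 single cultures, and neither was tested.

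The listed differences follow the level so closely that the table may reflect how its rows were selected more than which genes changed most. Around a curve common to both directions, the absolute log2 differences lay between 0.89 and 1.13 times the curve. The rho with the level was -0.98 in both the higher and the lower genes. A size limit set by the level in the authors' test could give such a rho, but alone it would set no upper bound. Any rows confined to p-values between 0.0346 and 0.0498 could give the same band, so the rho cannot decide how the test works. A list of every gene under a p of 0.05 from a calibrated test is argued against: even with no effect 80% of such p-values would lie below 0.04, or 188.8 of 236, and 40 did. Whether higher genes differed more than lower genes at equal level stays open: their median absolute log2 difference was larger by 0.39 and their median log2 ratio to the curve by 0.0068 ± 0.013 (bootstrap SD), but with the listed differences this close to 1 curve the selection of the rows fixes that ratio. Whether the test itself cannot give smaller p-values, or genes with larger differences at the same level lie outside these rows, stays open, and no biological explanation was tested.

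The offset at which higher and lower genes shared 1 curve was 0.003 ± 0.0066 log2 (SD over resamplings). Rows kept by a size limit alike in both directions would give an offset near 0 at any scaling. The value therefore does not measure the scaling between the libraries. All 7 listed genes on chromosome 20 were higher (BMP7, APCDD1L, CPXM1, EYA2, FAM217B, LRRN4 and STX16-NPEPL1), with differences from 1.43 (CPXM1) to 3.58, although CPXM1 was negative and BMP7 under 2-fold when centred on the median listed gene, and 619 of 10000 shuffles gave some one-sided chromosome with at least 7 listed genes. TIMP4 overlaps SYN2 on the opposite strand, and both were lower, by 4.4-fold and 3.85-fold. Of the 236 listed genes, 141 overlap a gene on the other strand and 68 a gene on the same strand in the annotation.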
